A study of Mus musculus with 2 samples.

How the data were processed

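H3K27me3, the trimethylated form of histone H3 lysine 27 that Polycomb repressive complex 2 writes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in limbs of mouse embryos of strain B6NCrl at 11.5 days of development. The labels give 1 group of 2 biological replicates, made from the pooled limbs of 109 and 88 embryos of both sexes, and each replicate joins the reads of its own technical replicates. No other tissue, stage or mark was analysed here, and the control libraries were not analysed here either, so every value is a property of the peaks called in this tissue.

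The deposited data are 4 peak lists on the mm10 build of the mouse genome, per the deposited notes on each file. There is 1 list for each replicate alone, 1 called on both replicates together (pooled) and 1 of replicated peaks. Both replicates were set against the same control alignments, per the deposited notes, so the replicates share the chance errors of that control. Every row of the replicated list is also a row of the pooled list. The aligner, the peak caller, its settings and the rule that made a pooled peak a replicated peak are not given in the sources used here. The authors' lists hold a fold enrichment over control for each peak, which is a linear ratio, and it was used only to describe and rank peaks within a list. The deposited lists also hold the −log10 of each peak's p and the −log10 of its q. The lists hold no read numbers, so the sequencing depth behind each replicate is unknown. The lowest −log10 p in any list was 2.03. Peaks outside chromosomes 1 to 19 and X were left out: 4 in replicate 1, 1 in replicate 2, 1 in the pooled list and 0 in the replicated list. No peak lay on the Y chromosome.

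Genes came from GENCODE mouse release M21 on GRCm38, the same build as the peaks, and 21755 protein-coding genes on those 20 chromosomes formed the background. The transcription start site (TSS) was the 5′ end of the gene record. A gene was called marked when a replicated peak overlapped the 1 kb on either side of its TSS by at least 1 bp. As a measure per replicate, the percent of the 5 kb on either side of the TSS covered by that replicate's own peaks was computed, and means are given with the SD of the replicates. For Hoxa3, Hoxc5, Hoxd3 and Hoxd4 the gene record reaches upstream over neighbouring genes, so the window lies away from the start most often drawn for the gene. TSSs were called CpG-rich when the 500 bp on either side had an observed to expected CpG ratio of at least 0.6 and at least 50% G and C.

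A peak counted as overlapped in the other replicate when at least 50% of its bases were covered there. Overlaps were tested by a circular permutation test, shifting the peaks of a list around each chromosome by a random distance, 1000 times, one-sided. The smallest p this gives is 0.001, and since shifted peaks can fall in assembly gaps the shifted overlap is slightly low. Lists and families of genes fixed before the data were examined were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 22 lists and, separately, the 26 families. An adjusted p under 0.05 was called. Genes are not independent replicates, because neighbours can share a peak, and how well reads map to repeated gene families was not tested. All 22 lists were matched to the annotation, where 2 symbols of the imprinted list proved to be names of 1 gene, leaving 19 members. Hox clusters were compared by permuting gene labels, with 100000 resamples or all splits. Replicated peaks no more than 3 kb apart were joined into domains. Intervals on shares are exact binomial 95% intervals and cover counting error only.

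The genes that could be named were also fixed beforehand by rule, and not each of them is named. They are any Hox gene, any member of both limb lists, from every other list up to 4 marked members with the highest coverage and up to 3 unmarked members with the lowest, the genes with a TSS in the 10 widest domains, and members of a list where a count of 5 or fewer is given. Alternatives fixed beforehand were another overlap (1 bp or 90%), a −log10 q of at least 2, equal numbers of peaks, joined peaks, wider or more fully covered TSS windows, CpG-rich TSSs alone, bases more than 10 kb from genes, and each replicate alone. Any annotated start of a protein-coding transcript as the TSS, leaving out the X chromosome, and the comparison of the limb lists with each other were added after the data had been seen.

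The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data first. For replicate overlap, 57127 simulated peaks sharing 40.0% with another set gave 40.5%, and an independent set gave a permutation p = 0.0995. For gene lists, of 200 simulated lists of 20 genes among 21755, 2% passed an unadjusted 0.05 when marked as often as the background, and 85% when 45% of the list was marked. For the Hox permutation, 2% of 50 simulated comparisons of 39 genes without a difference passed 0.05. Simulated genes were drawn independently, whereas real neighbours can share a peak, so these rates need not hold for them.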

Results

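H3K27me3 was mapped in the limb of the 11.5-day mouse embryo, when the limb bud is mostly undifferentiated mesenchyme under a sheet of ectoderm. Both replicates belong to the only group, so the comparisons are between replicates, between genes within this tissue and between chromosomes. On chromosomes 1 to 19 and X, replicate 1 held 57127 peaks covering 22.5 Mb and replicate 2 held 59561 peaks covering 27.6 Mb. The pooled list held 30094 peaks over 19.4 Mb and the replicated list 24209 peaks over 18 Mb, or 0.684% of the genome. Replicated peaks were narrow, with a median width of 391 bp, and 4365 of them (18%) were wider than 1 kb. Their median fold enrichment, as the authors' lists give it, was 3.44. The sequencing depth is unknown, so a gene without a peak is one where none was called.

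Replicated peaks gathered at gene starts and over exons. Of the 24209 peaks, 5116 (21.1%) touched the 1 kb on either side of a protein-coding TSS, against 2.24% of shifted peaks, a ratio of 9.45. A further 3386 peaks (14.0%) touched an exon away from a TSS, against 7.10% of shifted peaks. The share in introns was 27.3%, against 31.1% when shifted, and the share outside protein-coding genes was 37.6%, against 59.6%. By a one-sided circular permutation test the shares at TSSs and over exons had p = 0.001, the smallest 1000 shifts can give. In each replicate's own, longer list the share at TSSs was lower, 12.8% in replicate 1 and 12.4% in replicate 2, and it was 44.1% of replicated peaks within 5 kb of a TSS.

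In all, 3276 of 21755 protein-coding genes (15.1%) had a marked TSS. Replicate 1 alone marked 4242 genes and replicate 2 alone 4179, and 3391 genes were marked in both lists. Requiring a peak over at least 50% of the TSS window lowered the count to 1758. CpG-rich TSSs were marked more often than CpG-poor ones, with 1847 of 9739 (19%) against 1429 of 12016 (11.9%). The difference of 7.07 percentage points had p = 2.57e-47 by a two-sided Fisher's exact test.

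Whether the mark lay on developmental regulators of other tissues was asked with lists of genes. All 32 transcription factors of the central nervous system (CNS) were marked, with a mean of 77.9% ± 5.66 (SD, n = 2) of the 5 kb on either side of the TSS covered by peaks. Six3, a forebrain and eye regulator, had 97.7% ± 0.940 covered, Pax6, which is needed for eye and forebrain, 96.6% ± 4.82, and Olig2, of motor neuron and oligodendrocyte precursors, 96.6% ± 0.552. The lowest member of the list had 48.8%. Of 15 kidney and gonad genes, 13 were marked, among them Wt1 with 92.8% ± 0.926, Pax2 with 90% ± 1.27 and the podocyte gene Nphs1 with 89.4% ± 5.20. Both unmarked members, Slc12a1 and Umod, which encode proteins of the differentiated tubule, had 0% in each replicate. Of 19 genes of endoderm, liver and pancreas, 13 were marked, led by Neurog3 (93.8% ± 4.20), Cdx2 (93.5% ± 6.56), Onecut1 (92.2% ± 3.87) and Nkx2-1 (89.9% ± 5.22). The liver genes Alb, Afp and Hnf4a were unmarked and had no coverage in either replicate. Of 15 heart genes, 8 were marked. The cardiac regulators Nkx2-5 (86.8% ± 5.90), Hand1 (86.2% ± 8.88) and Tbx20 (85.0% ± 7.90) were among them, and the transcription factor gene Mef2c and the genes Myh6 and Nppa, which encode a myosin and a secreted peptide of heart muscle, were unmarked with 0%. Against all other protein-coding genes, of which 14.9% to 15.0% were marked, the adjusted p by Fisher's exact test was 9.45e-26 for the CNS list, 1.14e-08 for kidney and gonad, 8.13e-07 for endoderm and 0.00125 for heart.

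**Figure D1:**
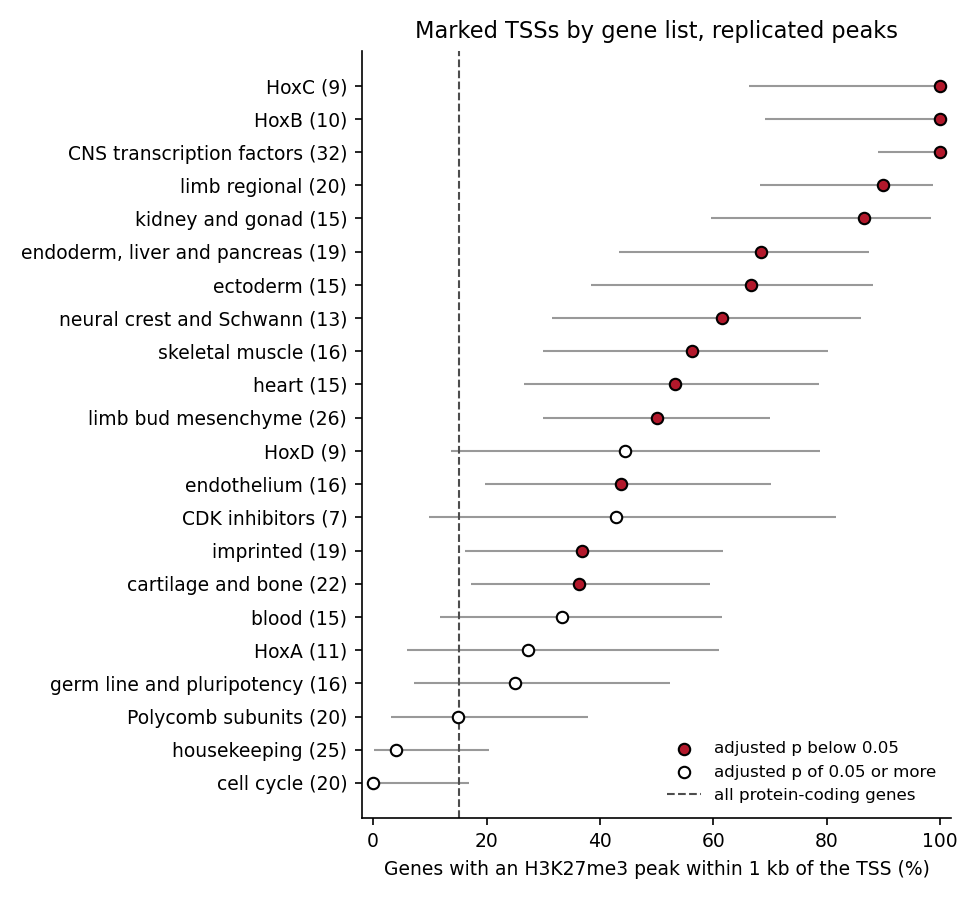
Percent of the genes of each of 22 lists (number of genes in brackets) with a replicated H3K27me3 peak within 1 kb of the TSS; bars are exact binomial 95% intervals and the dashed line is the 15.1% of all protein-coding genes. The CNS, HoxB and HoxC lists were marked at 100%, and the cell cycle list at 0%.

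Lists of genes from lineages that build or enter the limb were marked in part, and so was the imprinted list. Whole limbs were profiled, so a peak does not show in which cells the mark lay. Among 16 skeletal muscle genes 9 were marked, including Pax7 (96.3% ± 1.68), Pax3 (90.8% ± 6.29) and Lbx1 (90.1% ± 2.41), regulators of muscle precursors, and the myogenic factor Myod1 (56.2% ± 13.4). Actc1, Myf6 and Mymk were unmarked with 0%. Among 22 genes of cartilage and bone 8 were marked, with Ihh, the growth plate signal, at 83.2% ± 3.33, Nkx3-2 at 74.5% ± 15.9, and the cartilage matrix genes Comp at 62.2% ± 9.02 and Acan at 54.4% ± 6.92. The collagen genes Col10a1, Col11a1 and Col9a1 were unmarked with 0%. In the ectoderm list 10 of 15 genes were marked, among them Esrp1 (76.6% ± 8.33) and Sp8 (72.0% ± 16.9), while Trp63, Krt14 and Krt15 had 0%. In the list of neural crest and Schwann cells 8 of 13 were marked, led by Tfap2a (88.2% ± 2.40) and Foxd3 (79.2% ± 9.35). In the endothelium list 7 of 16 were marked, led by Sox7 (82.4% ± 5.22) and the VEGF receptor gene Flt1 (71.2% ± 12.8), while Pecam1, Eng and Egfl7 had 0%. Of 19 imprinted genes 7 were marked, led by Ascl2 (64.0% ± 8.12) and Grb10 (53.6% ± 20.8). The adjusted p of these lists by Fisher's exact test was 0.000364 for muscle, 0.0197 for cartilage and bone, 2.69e-05 for ectoderm, 0.000364 for neural crest, 0.0104 for endothelium and 0.0261 for imprinted genes. With a −log10 q of at least 2 the calls of cartilage and bone (exact adjusted p = 0.0684) and endothelium (0.0667) were lost. The calls of endothelium (0.112) and imprinted genes (0.0896) were lost with replicate 2 alone, and with CpG-rich TSSs alone that of neural crest was lost (0.242), with 2 of the 4 genes left (50%) marked. With CpG-rich TSSs alone 1 of 7 imprinted genes was marked (14.3%), against 19% of other genes (exact adjusted p = 1).

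Of 15 blood genes 5 were marked, Tal1 (81.1% ± 8.87), Ikzf1 (46.0% ± 6.56), Epor (38.5% ± 9.08), Gfi1b (22.8% ± 5.78) and Klf1 (7.73% ± 4.70), which did not pass the test (adjusted p = 0.0809, Fisher's exact test). The germ line and pluripotency list had 4 of 16 marked, Pou5f1, Nanog, Prm2 and Tdrd1 (exact adjusted p = 0.299). The cell cycle inhibitors had 3 of 7 marked, Cdkn2a at 78.3% ± 14.1, Cdkn2b at 59.8% ± 5.37 and Cdkn2c at 24.4% ± 4.35 (exact adjusted p = 0.0910). Among 20 genes of Polycomb subunits Cbx4 (62.3% ± 7.42), Phf19 (58.0% ± 12.3) and Rbbp7 (4.25% ± 2.64) were marked, close to the share of other genes (15.0% against 15.1%, exact adjusted p = 1). Of 25 housekeeping genes only Pgk1, on the X chromosome, was marked, with 5.03% ± 0.198 covered (exact adjusted p = 0.188). None of the 20 cell cycle genes was marked, which allows a share of up to 16.8% by the exact binomial 95% interval, and coverage was 0% throughout (exact adjusted p = 0.0809). That list was called lower with each replicate alone, at exact adjusted p = 0.0297 and 0.0295. The lists HoxA, HoxD, blood, germ line and CDK inhibitors were each called higher under at least 1 alternative.

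Of 26 families set by symbol, 18 were marked more often than other genes, 5 less often and 3 passed neither way. Every gene of the Pax (9), LIM homeobox (12), Nkx (14) and Irx (6) families was marked, and 16 of 19 Wnt, 28 of 44 Fox, 11 of 17 T-box, 11 of 19 Sox, 10 of 15 Pou, 5 of 6 Gata genes (all but Gata1) and 4 of the 6 genes Six1 to Six6 (Six1, Six2, Six3 and Six6). Among signals, 13 of 22 Fgf and 10 of 21 Bmp and Gdf genes were marked. Genes of neuronal excitability stood out as well, with 63 of 94 potassium channel genes (67%), 14 of 26 calcium channel genes and 30 of 46 genes of glutamate and GABA receptors (65.2%). Collagens (16 of 45) and solute carriers (81 of 371) were also above other genes. The adjusted p of these 18 families lay between 6.24e-29 and 0.00674 by Fisher's exact test. Below other genes were olfactory receptors (0 of 1135), vomeronasal receptors (0 of 331), ribosomal proteins (1 of 80, Rpl3), Zfp zinc finger genes (18 of 394) and histone genes (1 of 69, Hist3h2ba), with adjusted p from 6.57e-82 to 0.000412. Protocadherins (11 of 69), keratins (4 of 53) and proteasome genes (4 of 40) were not called; the marked members were Krt7, Krt8, Krt18 and Krt87, and Psmb8, Psmb9, Psmd5 and Psmd10. Single members of these families were named after their values were seen. Among CpG-rich TSSs alone, the call of the genes Six1 to Six6 was lost with 3 of 5 marked (60%, exact adjusted p = 0.0524), protocadherins were called higher (63.6% marked, 0.00187) and proteasome genes lower (3.33%, 0.0365).

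The design's tissue question was whether TSSs of genes used in limb mesenchyme were marked less often than those of another lineage. Of 26 genes of limb bud mesenchyme 13 were marked (50%), against all 32 of the CNS list, a difference of −50 percentage points (p = 3.30e-06, two-sided Fisher's exact test). With 50% of the TSS window covered the difference was −81.5 points. The CNS list holds transcription factors alone and had the highest share of the lineage lists. The shares of kidney and gonad (86.7%), endoderm (68.4%), ectoderm (66.7%), neural crest (61.5%), skeletal muscle (56.2%) and heart (53.3%) genes lay above that of limb mesenchyme, and those of endothelium (43.8%), cartilage and bone (36.4%) and blood (33.3%) genes below it. The differences of these lists from limb mesenchyme were not tested. No coverage at all was found at Prrx2, a homeobox gene of limb mesenchyme, at Gli2 and Gli3, which carry out Hedgehog signalling, at Pbx1, or at Fgf10, the mesenchymal signal for limb outgrowth. Prrx1 (1.85% ± 2.62), Wnt5a (2.08% ± 0.148), Etv5 (1.94% ± 2.74), Twist1 (3.86% ± 5.46) and Bmp7 (4.32% ± 1.03) were unmarked too. Meis1 and Meis2, homeobox genes of the proximal limb, were unmarked at the TSS with 23.8% ± 2.10 and 21.8% ± 6.69 of the wider window covered, and Osr1 had 21.6% ± 6.46. The marked members ranged widely. Irx3 had 92.1% ± 2.13 covered, Tbx2 77% ± 1.92, Tbx3 65.3% ± 5.15, Lhx2 63.5% ± 9.11, Irx5 61.1% ± 7.30, Msx1 48.6% ± 7.50 and Msx2 39.6% ± 4.99, whereas Lhx9 (23.0% ± 9.72), Sall1 (21.4% ± 5.23), Etv4 (11.7% ± 5.44), Twist2 (5.87% ± 5.61), Bmp4 (4.22% ± 1.02) and Sall4 (1.70% ± 2.40) had less. The replicates' own peaks disagreed at the TSSs of Sall4, Twist1 and Osr1. Sall4 and Osr1 were marked by replicate 1 alone, with 0% of the wider window covered at Sall4 in replicate 2, and Twist1 by replicate 2 alone. Compared with all other genes, the mesenchyme list was still marked more often (adjusted p = 8.24e-05), but not when 50% of the TSS window had to be covered (15.4% against 8.07%, exact adjusted p = 0.188).

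Genes of the limb regional list were marked more often than those of the mesenchyme list. Expression was not measured here, and the mesenchyme list holds regional genes too, such as Meis1 and Meis2 of the proximal limb. The comparison is thus between lists and does not test whether restricted activity goes with the mark. Of the 20 genes of the regional list 18 were marked (90%), a difference of 40 percentage points (p = 0.00495, two-sided Fisher's exact test, a comparison added after the lists were seen). The 5′ ends with most coverage were those of Pax9 (92.6% ± 1.87), En1 of the ventral ectoderm (85.6% ± 4.31), Fgf8 of the apical ectodermal ridge (78.2% ± 0.983) and Shh, the signal of the posterior margin (75% ± 6.57). Dlx6 had 70.5% ± 5.88 and Dlx5 52.5% ± 2.09. Among regulators of limb identity, Pitx1 and Tbx4 of the hindlimb had 68.7% ± 0.0778 and 23.8% ± 4.59, and Tbx5 of the forelimb had 57.8% ± 11.8. The dorsal genes Lmx1b and Wnt7a had 60% ± 0.707 and 66.2% ± 10.2. Alx4 had 59.6% ± 7.08. Lower values were found at Alx3 (28.2% ± 3.58), Ptch1 (27.5% ± 4.16), Hand2 (23.1% ± 1.51), Bmp2 (21.9% ± 12.2), Grem1 (15.6% ± 8.24) and Hhip, the lowest marked member (3.97% ± 2.22). Replicate 1's own peaks left the TSS of Hhip unmarked and marked 17 of the 20 genes, and replicate 2's marked 18. Gli1 and Fgf4 were unmarked, with 3.14% ± 4.43 and 11.1% ± 0.523. When 50% of the TSS window had to be covered, the difference between the limb lists was 24.6 points and no longer past the threshold (p = 0.0914, Fisher's exact test).

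The 4 Hox clusters differed. HoxB and HoxC were covered over more of their bases than HoxA and HoxD, and every HoxB and HoxC gene was marked. Over the HoxC cluster (chromosome 15, positions 102921103 to 103036852) peaks covered 73.6% ± 9.20 (SD, n = 2) of the bases, and over HoxB (chromosome 11, 96194316 to 96368256) 62.9% ± 4.45. Over HoxD (chromosome 2, 74668310 to 74765142) they covered 37.9% ± 6.31, and over HoxA (chromosome 6, 52155590 to 52260880) 16.8% ± 2.72. The 10 HoxB and 9 HoxC genes had between 60.8% ± 12.7 (Hoxc10) and 95.6% ± 1.31 (Hoxc12) of the 5 kb windows covered. The marked HoxA genes were Hoxa13 (49.6% ± 8.88), Hoxa1 (42.1% ± 9.84) and Hoxa4 (24.2% ± 1.21), and Hoxa2, with 27.1% ± 5.46, had no replicated peak within 1 kb of its TSS. The 7 genes Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and Hoxa11 had at most 8.70% ± 1.04. For Hoxa3 the window lies away from the start most often drawn, so its value does not describe that start. Hoxaas3, an antisense gene whose TSS lies within the Hoxa3 record, had 28.2% ± 0.530. In HoxD the 5′ genes Hoxd13 (51.6% ± 14.0), Hoxd11 (42.5% ± 2.60) and Hoxd12 (41.8% ± 4.94) had most coverage, followed by Hoxd1 at the 3′ end (34.0% ± 0.523), Hoxd10 (22.8% ± 9.44) and Hoxd9 (20.9% ± 15.0), and Hoxd8, Hoxd3 and Hoxd4 had 11.4% ± 6.5 or less. The windows of Hoxd3 and Hoxd4 lie away from the starts most often drawn, so their values do not describe those starts. Mir10b, whose TSS lies within the Hoxd4 record, had 50.1% ± 3.73.

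**Figure D2:**
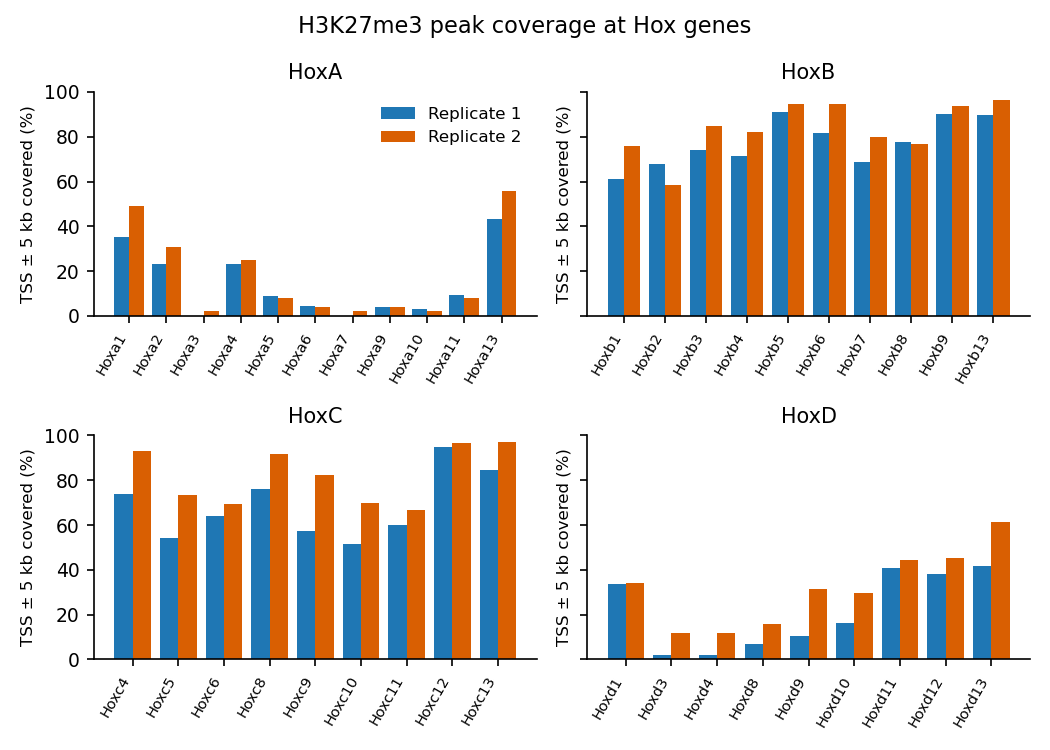
Percent of the 5 kb on either side of each Hox gene's TSS covered by the peaks of replicate 1 (blue) and replicate 2 (orange), genes ordered by paralogue number from 3′ to 5′. HoxB and HoxC genes lay between 51.8% and 97.1% in both replicates, and HoxA and HoxD genes between 0% and 61.5%.

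The mean over the 20 HoxA and HoxD genes was 20.6% and over the 19 HoxB and HoxC genes 78.1%, a difference of −57.5 points (two-sided permutation p = 1e-05, the smallest 100000 resamples can give). Genes of a cluster share domains, so this p is descriptive. Within HoxA and HoxD, paralogue groups 9 to 13 had a mean of 27.2% (9 genes) and groups 1 to 8 of 15.2% (11 genes), a difference of 12 points that did not pass the exact permutation test (p = 0.130, two-sided). Groups 1 to 8 include Hoxa3, Hoxd3 and Hoxd4, whose windows lie away from the starts most often drawn. How far this placement makes the difference was not tested. Counts of marked HoxA and HoxD genes depended on the list: 3 of 11 HoxA genes were marked by replicated peaks, 4 by replicate 1 and 6 by replicate 2, and 4 of 9 HoxD genes by replicated peaks, 9 by replicate 1 and 7 by replicate 2. The HoxD genes left unmarked by replicate 2 were Hoxd3 and Hoxd4, whose TSSs (74711927 and 74711929) nearly coincide. Their windows had the same coverage and entered these counts and the permutation tests as separate genes. As a list, HoxA was not called against other genes (adjusted p = 0.245, Fisher's exact test), nor was HoxD (0.0504). With replicate 2 alone both were called (0.0149 and 0.000480), and with replicate 1 alone HoxD was (1.27e-06). With any annotated start as TSS, 6 of 9 HoxD genes were marked and the list was called (adjusted p = 0.00247, Fisher's exact test). On the same rule 4 of 11 HoxA genes were marked, and that list was not called (0.105).

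Joining replicated peaks no more than 3 kb apart gave 8505 domains with a median width of 1421 bp, of which 523 were at least 10 kb wide. The widest, 139.9 kb on chromosome 15 (102905208 to 103045099), held the TSSs of all 9 HoxC genes, and the next, 107.3 kb on chromosome 11 (96250087 to 96357423), held those of Hoxb2 to Hoxb9. The domain of rank 3 (104.4 kb, chromosome 8, 91615245 to 91719628) held no protein-coding TSS. It lay over Fto, with Irx3 the nearest TSS, 82.4 kb away. The others of the 10 widest held the TSSs of Zic1 and Zic4 (74.9 kb, chromosome 9), Nfix (66.8 kb, chromosome 8), Pax7 (66.1 kb, chromosome 4), Pkdcc (60.4 kb, chromosome 17), Dmbx1 (55.2 kb, chromosome 4) and Six3 (48.6 kb, chromosome 17), and a domain of 48.9 kb without a TSS lay 77.2 kb from Pkdcc. Each of the 10 was covered by peaks of both replicates, over 33.7% to 79.7% of its length in replicate 1 and 48.2% to 86.2% in replicate 2. Joined within 10 kb, the widest domain was 284.5 kb.

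The strongest peaks of each replicate mostly repeated in the other, and most weak peaks did not. Among the 10% of replicate 1's peaks with the highest fold enrichment 96.1% were overlapped in replicate 2, and among the lowest 10% 24.0%. For replicate 2's peaks the values were 86.9% and 11.2%. Over all peaks, 22834 of 57127 in replicate 1 (40%) were overlapped by replicate 2, against 1.14% of shifted peaks, and 16552 of 59561 in replicate 2 (27.8%) by replicate 1, against 0.892%. The covered bases had a Jaccard index (shared over total bases) of 0.368, against 0.00532 when shifted. All of these had p = 0.001 by the one-sided circular permutation test. The overlap depended on its definition, from 46.9% (1 bp) to 25% (90%) for replicate 1 and from 38.6% to 9.18% for replicate 2. For replicate 1 it was 24.8% when peaks within 3 kb were joined and 49.0% at a −log10 q of at least 2.

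**Figure D3:**
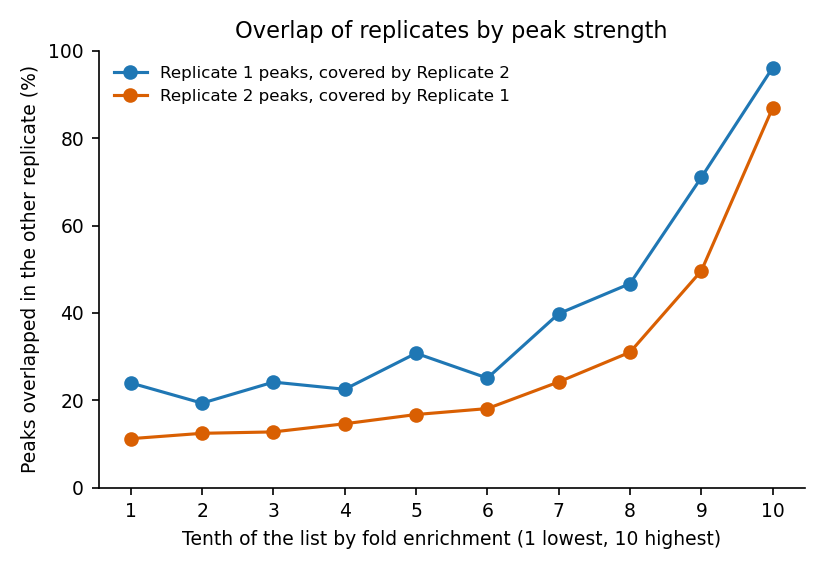
Percent of each replicate's peaks with at least 50% of their bases covered by the other replicate's peaks, by decile of the list in order of the authors' fold enrichment (1 lowest, 10 highest). It rose to 96.1% for replicate 1 and 86.9% for replicate 2 in the highest decile.

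Of 30094 pooled peaks, 24209 (80.4%, exact binomial 95% interval 80.0% to 80.9%) were in the replicated list. Of those, 74.8% had at least 50% of their bases covered by each replicate's own peaks, against 0.136% of the 5885 pooled peaks left out. The rule behind the replicated list is not given and may itself be an overlap of this kind. The contrast therefore describes the list and is no separate evidence that its peaks repeat. The peaks left out were narrower, with a median of 219 bp against 391 bp, and had a lower median fold enrichment, 2.82 against 3.44.

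Because both sexes were pooled, the X chromosome was compared with the autosomes. In replicate 2 peaks covered 1.74% of the X, second among 20 chromosomes, against an autosomal median of 1.05% and a range of 0.514% to 1.78%. In replicate 1 they covered 0.953%, rank 9, against a median of 0.915%. The exact one-sided rank p was 0.1 for replicate 2 and 0.45 for replicate 1. A rank among 20 chromosomes cannot give a p under 0.05, so no outcome could pass the threshold and these ranks are descriptive. In bases more than 10 kb from genes the X ranked first in replicate 2 (0.894%, exact p = 0.05) and had rank 5 in replicate 1 (0.461%, p = 0.25). In the replicated list it covered 0.666%, below the autosomal median of 0.710%, and ranked 11. The ratio of replicate 2 to replicate 1 was 1.82 on the X and 1.13 to 1.22 on the autosomes. The X held 9859 peaks in replicate 2 and 5830 in replicate 1. By peaks per Mb it ranked first in replicate 2 (57.6, against an autosomal median of 19.1, exact one-sided p = 0.05) and second in replicate 1 (34.1 against 21.1, p = 0.1).

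**Figure D4:**
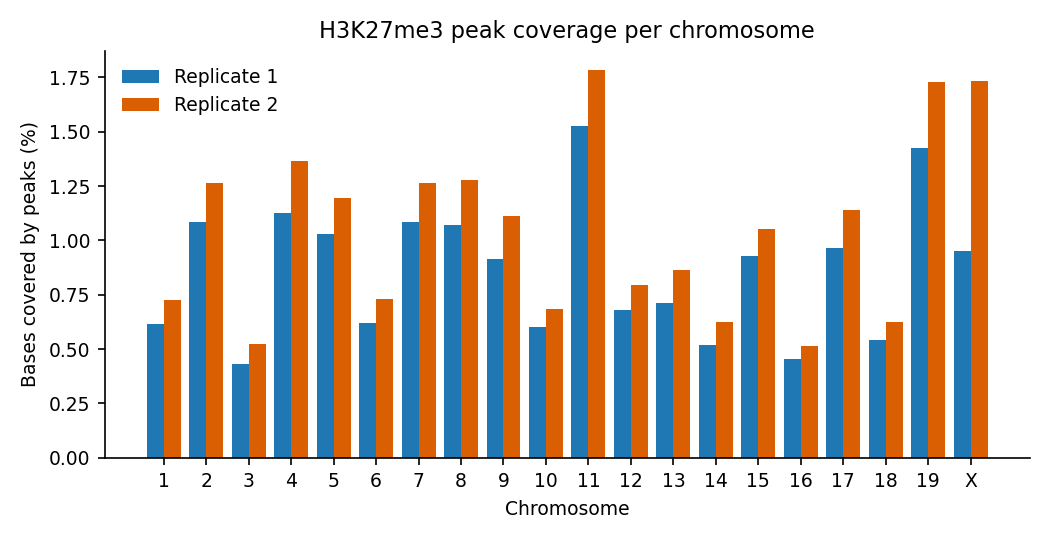
Percent of the bases of each chromosome covered by the peaks of replicate 1 (blue) and replicate 2 (orange). The X had 0.953% covered in replicate 1 and 1.74% in replicate 2, a larger ratio than on any autosome.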

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

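Peaks on scaffolds outside the main chromosomes entered no comparison. Replicate 1 held 4 of them, replicate 2 held 1 and the pooled list 1. The 4 are given because they exceed the 3 that a count of 0 allows, but no number of such peaks was predicted among 57131, and no test was run.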

How the results depend on the processing

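Any annotated start as TSS, leaving out the X and every setting of the comparison between the limb lists were chosen after seeing the data. Under all settings run, the overlaps between replicates, the Jaccard index, the share of peaks at TSSs, the limb and CNS difference, the CpG difference and the Hox cluster difference kept their direction and passed the threshold, and the 5′ against 3′ Hox difference never passed (p from 0.123 to 0.423). Of the 14 lists and 23 families called, 9 and 21 were called in every setting that could be run on them, and 6 lists and 2 families were called in another setting only. With CpG-rich TSSs alone no olfactory receptor and 1 vomeronasal receptor remained, which tests neither family. Some values moved. With a −log10 q of at least 2, 97.6% of pooled peaks were in the replicated list. Without that threshold, 60.2% of all pooled peaks had 50% of their bases covered in both replicates. With 50% of the TSS window, 1758 genes were marked, and the difference between limb lists was 24.6 points (exact p = 0.0914). With 1 bp of overlap the highest decile repeated at 97.7% in replicate 1 and 95.5% in replicate 2. The widest domain was 103.3 kb when peaks were joined within 1 kb, 284.5 kb within 10 kb, and 141.1 to 142.1 kb with either replicate alone. With CpG-rich TSSs alone 1 of 7 imprinted genes was marked (14.3%), below other genes at 19%, with no difference detectable (exact adjusted p = 1). A fuller window, a wider or narrower joining distance and a 1 bp overlap move these values by construction; for the others the cause was not tested. The X over the autosomal median was 1.36, with 1.04 and 1.65 for the replicates alone, 0.938 for the replicated list and 1.70 in bases more than 10 kb from genes, where replicate 2 alone had 2.10. Unknown depth limits every count of unmarked genes.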

Other observations

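The values of non-coding genes, the comparison of X-linked with autosomal TSSs, the ratio of X coverage between replicates and the test of bare TSSs were chosen after the data were seen, and the non-coding genes named were chosen after their values were seen. TSSs of 314 of 5305 lincRNA genes (5.92%) and 338 of 2958 antisense genes (11.4%) were marked by replicated peaks, against 15.1% of protein-coding genes. Away from protein-coding TSSs by more than 5 kb, the values were 4.13% and 5.52%. Of 2196 microRNA genes, 117 (5.33%) were marked. Among those known from neurons, Mir9-3 had 99.5% ± 0.177 (SD, n = 2) of the 5 kb on either side covered, Mir9-1 94.0% ± 3.39, Mir124a-3 77.2% ± 3.10, Mir124a-1 71.1% ± 8.72, Mir124a-2 56.4% ± 6.70 and Mir9-2 39.7% ± 4.63. Among those known from muscle and liver, Mir1a-1 was marked, with 45.2% ± 4.50 covered, and Mir1a-2, Mir206, Mir133b and Mir122 had 0%. Within the Hox clusters, Hotair (HoxC) had 64.1% ± 12.8, Mir196a-1 (HoxB) 78.2% ± 12.4 and Hottip, beside Hoxa13, 55.4% ± 7.88, while Mir196b in the middle of HoxA had 4.06% ± 0.0141. Imprinted H19 and Meg3 and the X-inactivation RNA Xist had 0% in both replicates.

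X-linked genes were marked often. Of 227 CpG-rich TSSs on the X, 99 (43.6%) had a replicated peak, against 1748 of 9512 (18.4%) on the autosomes (p = 7.41e-18, two-sided Fisher's exact test), and the values were 50.7% against 23.2% in replicate 1 and 55.5% against 22.0% in replicate 2. For CpG-poor TSSs the direction turned with the list. They were marked more often on the X in replicate 1 (19.4% against 15.7%, exact p = 0.0101) and replicate 2 (23.3% against 15.9%, p = 5.46e-07), at 13% against 11.8% with replicated peaks (p = 0.342), and less often at a −log10 q of at least 2 (6.80% against 9.53%, p = 0.0145).

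If weak peaks near the threshold were the whole of the difference at CpG-rich TSSs, it would have gone at a −log10 q of at least 2; it shrank but stayed, with 62 of 227 (27.3%) marked on the X against 1511 of 9512 (15.9%) on the autosomes (p = 1.50e-05, Fisher's exact test), so peaks under that threshold carried part of it. A candidate explanation is H3K27me3 on the inactive X of female cells, which would spare genes that escape inactivation. Of 5 such genes (Ddx3x, Kdm6a, Eif2s3x, Pbdc1 and Kdm5c) 0 were marked in replicate 2, against 52.8% of 250 other X genes with a CpG ratio of at least 0.6 (one-sided Fisher's exact p = 0.0250). The same exact comparison gave p = 0.230 in replicate 1, where Kdm5c was marked, and 0.0809 with replicated peaks, so the difference rests on 5 genes in 1 replicate. Kdm5c had 4.41% of the 5 kb on either side covered in replicate 1 and 6.42% in replicate 2. The genes were not matched for expression. Replicate 2's peaks also marked only 2 of 25 housekeeping genes, but 23 of the 25 lie on autosomes and are no like comparison for X genes. With replicated peaks 0 of those 23 were marked, and of the X-linked members only Pgk1 was. Active genes could be bare with or without an inactive X, so the comparison of escape genes with other X genes cannot decide the question.

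A gain of calls on all chromosomes alike would put the X among the autosomes, but its ratio between replicates, 1.82, lay above the highest autosome at 1.22. A larger share of female embryos in that pool may raise both the number of X copies, set against a shared control, and the number of inactive X chromosomes. Those explanations, and a threshold effect on widespread weak signal, cannot be told apart, because the lists hold no read numbers and the labels give no sex counts.

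Some limb genes seemed to carry the mark beside a bare TSS, as a first look at the replicated list had it. Among CpG-rich TSSs with 10% to 30% of the wider window covered, 6 of 9 genes of the limb bud mesenchyme, HoxA and HoxD lists had no replicated peak within 1 kb (Meis1, Meis2, Hoxa2, Hoxd8, Hoxd9 and Hoxd10), against 98 of 811 others (p = 0.000222, Fisher's exact test). Another annotated start carried the mark in 0 of the 6. With each replicate's own peaks only Meis1 and Meis2 were bare, 2 of 9 (exact p = 0.225 and 0.204), since both replicates marked the 4 Hox genes. For the mesenchyme list alone, 2 of 4 were bare (p = 0.0525 in replicate 1, 0.0466 in replicate 2, 0.0246 for bare in both and 0.0758 with replicated peaks, all exact and unadjusted), so whether low coverage alone could leave these 2 windows bare is open.

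The pooled list was shorter than that of either replicate, 30094 peaks against 57127 and 59561. The peak with the highest −log10 p in the pooled list (54.6, chromosome 5, 146261098 to 146261484, in Cdk8) had a fold enrichment of 5.78, above that list's median of 3.30. Those of rank 4 and 9 by −log10 p (chromosome 17, 39843010 to 39846782 and 39847997 to 39848904) had 2.26 and 2.21, below it. The chromosome 17 peaks lay over Gm26917, CT010467.1, Gm42418 and AY036118. All of these peaks were picked for a −log10 p that was high relative to their fold enrichment. Whether they are sites of the mark or errors of mapping was not tested.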
